A study of Pan paniscus with 11 samples.

How the data were processed

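Gene expression was measured in cultured fibroblasts of bonobos (Pan paniscus), with 1 array per culture and 11 arrays in all. Per the labels, 10 lines came from 10 animals, 5 female and 5 male, aged 2 to 20 years, and were grown and harvested under standard conditions. A second culture of male line 1 was harvested at 50% confluence. Lines were grouped by the sex in the labels and numbered within each group in accession order, so the numbers pair nothing. P-values measure the spread between lines of different animals, with 1 culture per line, so biological and technical spread are not separated.

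The deposited values are intensities on a linear scale, 1 whole number per probe set, for 12625 probe sets of an Affymetrix human array (probe annotation of 2016). How the authors summarised probes and scaled the arrays is not given in the sources used here. The values show that low intensities were raised to a floor before deposit. The lowest intensity was 100 in 9 arrays. In male line 5, 2321 probe sets had an intensity of 90, as had 2072 in the 50% confluence culture, and 0 lay between 90 and 100. After trimming 2%, array means ran from 408 to 423, a spread of 3.57%.

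The planned tests, lists and alternatives were fixed before the data were examined, and those added later are named as such where given. The preset rule kept the deposited scaling where trimmed means lay within 5% of each other, which held. A floor was set at the 40th percentile of all values, which was 100, and log2 was taken. The 67 control probe sets were left out. Of the other 12558, the 7333 above the floor in at least 5 of the 11 arrays were tested. Between 52.1% and 60.9% of probe sets lay above the floor per array. The number of arrays, not a read depth, limits the precision, and a gene at the floor has only an upper bound.

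Gene symbols came from the probe annotation. It gave 1 symbol for 10943 probe sets, several for 545 and none for 1070, and probe sets with several symbols were not named. Of 8226 distinct symbols, 7680 were found in a bonobo gene table of assembly NHGRI_mPanPan1-v2.0_pri, used for names alone. Where a gene had several probe sets, the one with the highest mean log2 over the 11 arrays stood for it, which gave 5370 genes. The probes follow human sequences, so differences from the bonobo sequence can lower a signal.

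Sex and age were fitted jointly with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend) over the 10 standard lines, and sex by age in a further fit. Adjusted p is Benjamini-Hochberg over the 7333 probe sets, with a threshold of 0.05, two-sided. Age slopes are given as the log2 change over 10 years. For 26 gene lists of 903 genes, limma's camera was run with its preset correlation of 0.01, and with an estimated correlation and fry as alternatives; adjusted p for lists is over the lists tested. The 2 cultures of male line 1 have no replicates, so their difference was described without a test, and the median of a list's members above the floor in both cultures was set against 10000 random lists of the same size matched on mean expression in 20 bins. Distance between arrays is the root mean square log2 difference over tested probe sets. Variation is the SD of log2 intensity over the 10 lines.

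Genes were named by rule: up to 15 in each direction past the threshold and, with fewer than 10, also the 10 of lowest p; all tested genes of the X and Y lists; the 15 largest increases and 15 largest decreases by harvest state among genes above the floor in both cultures; the 20 genes of largest SD; and 2 to 4 members of largest change for a described list. Alternatives were quantile normalization, median centring, other floors (20th and 60th percentile), a pseudocount of 50, other filters, other variance models, other codings of age, and leaving out each line. The fits were checked on simulated data made from the means and spreads of the 7333 probe sets. For sex, 38% of 100 probe sets changed by 1 log2 and 92% of 100 changed by 2 log2 were recovered. For age, the shares were 66% and 97% for the same change over 10 years. False calls numbered 2 for sex and 8 for age, counted once over both sizes. All changes were planted together, which eases the adjusted threshold, and noise was drawn independently for each probe set. The recovered shares can therefore overstate recovery in the real fits, which gave few calls.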

Results

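Fibroblast cultures from 10 bonobos were profiled on 1 array each, with a further culture of 1 of the lines harvested at 50% confluence. Female lines 1 to 5 came from animals aged 9, 2, 4, 20 and 20 years, and male lines 1 to 5 from animals aged 4, 2, 12, 17 and 19 years. Fibroblast genes were strongly expressed throughout. Of 21 fibroblast identity genes on the array, 20 were above the floor in all 11 cultures, led by the intermediate filament gene VIM with a median intensity of 27164 and the collagen gene COL1A2 with 19602. The median intensity of endothelial, melanocyte and blood cell markers was 100, the floor. That of keratinocyte and epithelial markers was 121, with 6 of 23 above the floor in all 11 cultures, among them KRT7 (1618) and KRT8 (868). Array quality differed. Control probe sets for 18S ribosomal RNA read 1508 to 2611 in the 50% confluence culture and 146 to 313 in male line 4, against 100 in 8 of the other lines and up to 171 in male line 2. Male line 4 also had the highest ACTB 3' to 5' ratio, 2.27, and the highest mean distance to the other lines, 0.804.

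The first comparison asked which genes differed between female and male lines. RPS4Y1, a Y-linked ribosomal protein gene, had an intensity of 1663 ± 297 (SD, n = 5) in males and was at the floor in all 5 females, so it was at least 16.4-fold higher. DDX3Y, a Y-linked RNA helicase gene, had an intensity of 291 ± 58.4 (SD, n = 5) in males and was at the floor in all females, at least 2.87-fold higher. KDM5D, a Y-linked histone demethylase gene, and NLGN4Y were above the floor in 4 of 5 males and 0 females. Male KDM5D intensities were 100, 176, 227, 133 and 187 in male lines 1 to 5, and those of NLGN4Y were 201, 127, 100, 163 and 247. EIF1AY was above the floor in male line 4 alone (193), and UTY in male line 3 (126) and male line 4 (110). SRY, ZFY, USP9Y and TXLNGY were not above the floor in any line. TMSB4Y, PRKY and AMELY gave signal in both sexes.

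**Figure D1:**
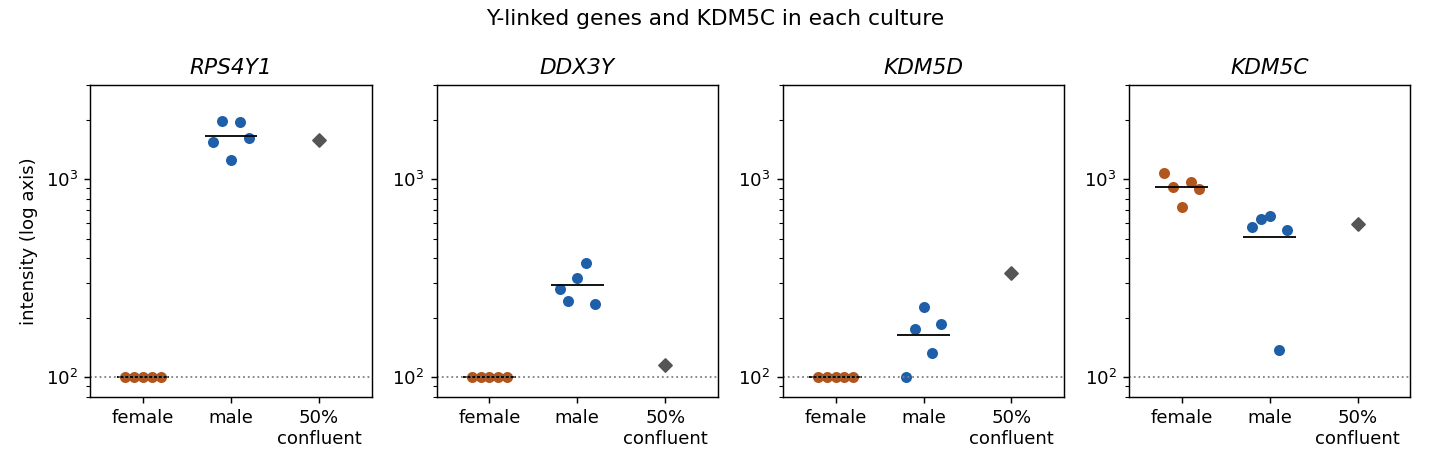
Intensity (log axis) of RPS4Y1, DDX3Y, KDM5D and the X-linked KDM5C in 5 female lines, 5 male lines and the culture of male line 1 harvested at 50% confluence. Each point is a culture, black lines are group means and the dotted line is the floor of 100; females sit at the floor for the Y-linked genes, and male line 4 has the lowest KDM5C, 137.

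Of 7333 probe sets tested with limma, 2 differed between the sexes, both higher in males. The log2 differences were 4.04 ± 0.24 (SE) for RPS4Y1 (adjusted p = 4.63e-07) and 1.52 ± 0.23 for DDX3Y (adjusted p = 0.0421). At an unadjusted p under 0.05 there were 171 probe sets, fewer than the 367 that chance alone would give. Adjusted over the list alone, 4 of 7 tested Y-linked genes passed. Among genes of lowest p that did not pass, CYCS, the gene of the electron carrier cytochrome c, read 2699 to 5219 in females and 432 to 3496 in males, a log2 difference of -1.74. The stem cell receptor gene LGR5 (-0.82) and the antisense transcript WT1-AS (-0.95) were lower in males by this estimate, as was TCL1B, with 181 to 361 in females and 100 to 207 in males. PMPCA (0.83), PTOV1-AS1 (0.84), PLCL2 (0.78) and CCNB2 (1.23), the gene of a mitotic cyclin, were higher. None of these 8 passed. DDX3Y did not pass when any line other than male line 5 was left out (adjusted p up to 0.271), which left RPS4Y1 as the 1 call.

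By camera, 3 of 26 lists differed by sex, and 1 with an estimated correlation, the Y-linked list. The Y-linked list was higher in males (adjusted p = 5.47e-09; 0.00917 as the adjusted p with an estimated correlation). Genes of the X chromosome that often escape inactivation had a median log2 difference of -0.39, with 10 of 15 lower in males and 0 passing singly. The histone demethylase gene KDM5C had an intensity of 917 ± 130 in females and 511 ± 212 in males (SD, n = 5), with 137 in male line 4 and 558 to 650 in the other males. PUDP had 393 ± 42.7 in females and 234 ± 75.8 in males, with 100 in male line 3 and 253 to 280 in the other males. EIF1AX (-0.58), AP1S2 (-0.54), SMC1A (-0.48), DDX3X (-0.47), EIF2S3 (-0.44), RPS4X (-0.39) and UBA1 (-0.17) went the same way, whereas TBL1X (0.29), USP9X (0.30), OFD1 (0.13), CD99 (0.10) and PRKX (0.08) were higher in males and STS was close to 0 (-0.05). Another probe set went the other way for USP9X (-0.18) and for DDX3X (0.07). The list's camera adjusted p was 0.0069, 0.0667 without female line 2, and 0.116 as the adjusted p with an estimated correlation. XIST, the RNA that coats the inactive X chromosome, was at the floor in all females and males. The mitosis list was higher in males, with 28 of 31 genes positive and a median log2 difference of 0.70, including CDKN3 (1.24), CCNB1 (1.20), UBE2C (1.18) and CDC20 (1.05), 0 of them passing singly. Its camera adjusted p was 1.52e-11, but the adjusted p was 0.788 with an estimated correlation, which was 0.70 between its genes.

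The second comparison asked which genes changed with donor age. No probe set passed with limma, and 251 had an unadjusted p under 0.05, against 367 by chance; the lowest adjusted p was 0.834. Among the 10 genes of lowest p, which did not pass, POSTN, which encodes the matrix protein periostin, had an estimate of -1.02 per 10 years, with 9337 in female line 2 and 942 in female line 5. COL3A1, a fibrillar collagen gene, had -0.76, and the secreted-protein gene ISLR -1.10. CTIF (-0.85) was at the floor in 4 of the 10 lines, all from animals of 17 years or more. The prostaglandin-degrading enzyme gene HPGD had -0.90. Positive estimates were seen for CCN5 (1.33), TFAP2A (1.30), LGALS3BP (1.22), SNPH and MTSS1. CCN5 read 682 in female line 2 and 17852 in female line 4, but 2666 in female line 5, also aged 20 years, and 6515 in female line 1.

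Camera called 4 lists by age, none of which passed with an estimated correlation. The heat shock and unfolded protein response list fell, with 21 of 26 genes negative and a median of -0.14 per 10 years (adjusted p = 8.41e-04; adjusted p = 0.180 with an estimated correlation). Its largest estimates were those of the asparagine synthetase gene ASNS (-0.94), HSPA2 (-0.75) and DDIT3 (-0.61). The interferon response list had 19 of 24 genes positive (adjusted p = 0.00439; 0.439 as the adjusted p with an estimated correlation), led by LGALS3BP (1.22) and the antigen processing genes PSMB8 (0.71) and TAP1 (0.62). Of the metallothionein and oxidative stress list, 19 of 27 were positive (adjusted p = 0.00694; 0.180 with an estimated correlation, also an adjusted p), among them the metal-binding protein genes MT1X (0.67) and MT1F (0.57). The cholesterol and fatty acid synthesis list had 15 of 20 positive (adjusted p = 0.0176; adjusted p = 0.409 with an estimated correlation), with FADS2 at 0.91 and DHCR7 at 0.50. Without female line 2 the interferon list had an adjusted p of 0.245, and the metallothionein and cholesterol lists did not pass either. The metallothionein list was also lost without female line 5, and the cholesterol list without male line 2, female line 3 or female line 5 (adjusted p up to 0.151). Single members of these lists did not pass over all probe sets. Adjusted over the list alone, LGALS3BP passed in the interferon list, as did 2 genes in the matrix list and 1 in the fibroblast identity list, neither of which camera called (adjusted p = 0.102 and 0.699).

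The age slope was then compared between the sexes. MMP1, which encodes the interstitial collagenase that cleaves fibrillar collagen, was the 1 probe set that passed. Female lines 1 to 3, aged 9, 2 and 4 years, read 1356, 951 and 602, and female lines 4 and 5, aged 20 years, read 12032 and 8220. Male lines 1 to 3, aged 4, 2 and 12 years, read 7243, 8128 and 7471, and male lines 4 and 5, aged 17 and 19 years, read 382 and 778. The male slope minus the female slope was -4.53 ± 0.63 (SE) log2 per 10 years (limma, adjusted p = 0.0458), and 355 probe sets had an unadjusted p under 0.05, against 367 by chance. Genes of lowest p that did not pass included the mitotic genes PTTG1 and CDKN3, the growth factor antagonist gene GREM1, and LPXN, ADGRB1, SH3BGR, FNBP1, CEACAM3 and SAT1. The MMP1 call was lost in 5 of 9 other settings: quantile normalization (adjusted p = 0.124), median centring (0.0710), array weights (0.0851), no intensity trend (0.169) and all probe sets (0.736). It was also lost when any line other than male line 3 was left out, with estimates from -4.89 to -3.96 and an adjusted p of up to 0.353.

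**Figure D2:**
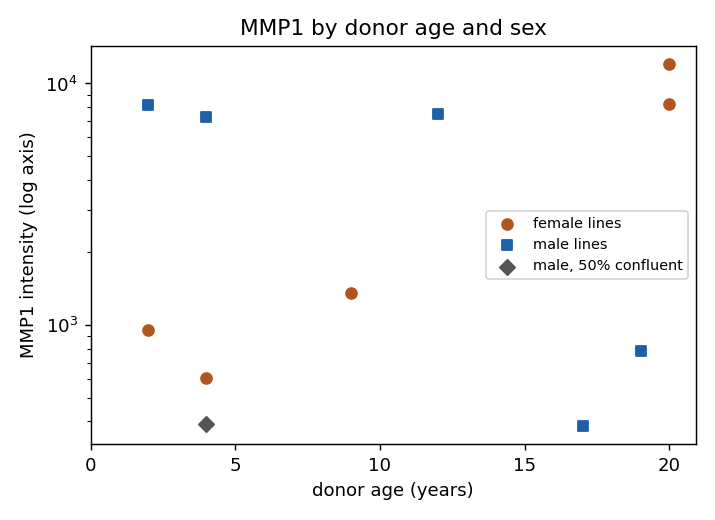
MMP1 intensity (log axis) against donor age in years for 5 female lines, 5 male lines and the culture of male line 1 harvested at 50% confluence, 1 point per culture. Female lines aged 20 years read 8220 and 12032, and male lines aged 17 and 19 years read 382 and 778.

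Harvest state was compared in male line 1, whose standard culture the labels set against the culture taken at 50% confluence. The labels give neither the confluence of the standard culture nor the passage numbers, so the size of the density contrast is unknown. MMP1 was 18.6-fold lower at 50% confluence (7243 against 390, the standard culture first in each pair). Other genes lower by over 4-fold included APOE, a lipid carrier (2010 against 230), MFAP4 (2063 against 268), the basement membrane collagen COL4A1 (2491 against 346), the proteoglycan aggrecan ACAN (813 against 135), TNC (2503 against 427), GPC3 (2166 against 443) and the receptors IL1RL1 (1600 against 223) and NOTCH3 (2223 against 480). DENND2B, PLPP3, SOD3, RUNX1T1, PTX3 and RALB made up the 15 largest decreases among genes above the floor in both cultures, of which DENND2B (19720 against 2505), PLPP3, RUNX1T1 and RALB lay outside the range of the 10 standard lines. A second probe set of DENND2B stood at -0.88 and one of RALB at -0.21, smaller decreases than those ranked here. Genes higher at 50% confluence included TP53I11 (116 against 958), the collagen genes COL10A1 (258 against 1864) and COL11A1 (1964 against 8588), the microfibril gene MFAP5 (409 against 2123), the cardiac actin gene ACTC1 (2842 against 12754) and the smooth muscle myosin gene MYH11 (874 against 3997), whose 4 probe sets were all higher. SERPINB7, PCYT2, HEBP2, ADGRL2, AHNAK2, DAPK1, DHRS3, the metallothionein gene MT1X and CTSW completed the 15 largest increases, and a second probe set of ADGRL2 went the other way (-0.10). Over 4 other scalings and floors, the lowest log2 differences were 1.33 for ADGRL2 (2.23 as deposited), 1.38 for DAPK1 (2.11) and 1.10 for CTSW (2.03). The decrease of RALB shrank to as little as -1.23 (-2.06 as deposited).

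In all, 300 probe sets were over 2-fold higher and 292 over 2-fold lower among 6147 above the floor in both cultures, 9.63%. The balance depended on scaling, with 277 higher and 306 lower under quantile normalization and 260 and 325 with median centring. Of the 592 as deposited, 261 also lay outside the range of the 10 standard lines. Between different standard lines the share over 2-fold was 6.43% to 19.2% (median 10.5%), with 18 of 45 pairs below 9.63%. Between the 50% confluence culture and the other standard lines the share was higher than 9.63%, at 10.9% to 17.0%. There was 1 culture per state, so the differences have no replicate check, and the 50% confluence array was the one with the strongest ribosomal RNA control signal.

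By gene list, DNA replication genes stood lowest at 50% confluence. Of 27 measured, 25 were lower, 10 by over 2-fold, with a median log2 difference of -0.76, below all 10000 matched random lists. These lists held members above the floor in both cultures. Random lists hold unrelated genes, but the estimated correlation between members was 0.54 for DNA replication and 0.30 for oxidative phosphorylation. Percentiles in this paragraph therefore do not measure chance. The other 9 tested replication genes were above it in the standard culture and at it at 50% confluence, and with members above the floor in either culture, an alternative chosen after seeing the data, 34 of 36 were lower (median -0.84). The replication factor genes RFC2 (335 against 111) and MCM4 (580 against 206), the chromatin assembly gene CHAF1A (550 against 180) and the transcription factor gene E2F1 (407 against 156) were among them. The mitosis list had a median of 0.00, with 13 of 27 higher and 13 lower. Immediate early genes were lower in 24 of 27 (median -0.30, percentile 0.82), with DUSP2 (-1.90), IER2 (-1.81) and JUNB (-1.57) the farthest. Growth factor signalling (median -0.47, percentile 0.10), fibroblast identity (-0.30, percentile 0.81) and matrix genes (-0.19, percentile 1.02) were also low. Of their members, 12 of 19, 14 of 21 and 26 of 42 were lower, respectively. PDGFRB (-1.31), FBLN1 (-1.54), COL4A1 (-2.85) and COL4A2 (-1.98) were among these. COL11A1 (2.13), THBS1 (1.53), GREM1 (1.19) and FZD7 (1.17) went the other way. Oxidative phosphorylation genes were higher in 39 of 49 (median 0.29, percentile 99.96), among them NDUFB1 (1.43), COX6C (1.36) and COX7B (440 against 1248). Cell cycle arrest genes had a median of 0.55 (percentile 99.93), with CCNG1 at 1.55 and the inhibitor gene CDKN1A at 0.96, whereas GAS1 stood at -1.49. This median reversed to -0.035 with a floor at the 60th percentile, so its direction is not settled. Contractile genes had a median of 0.39 (percentile 99.8), with MYH11 (2.19), CNN1 (1.67) and MYLK (1.38), and TGFB1 at -1.75. The metallothionein list had a median of 0.30 (percentile 98.8), with MT1X (2.03) and MT1H (898 against 2547) higher and SOD3 lower (-2.32), but with members above the floor in either culture it lay inside the random range (0.22, percentile 96.2). The growth factor list then had -0.28 at percentile 2.48, close to the edge of that range.

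**Figure D3:**
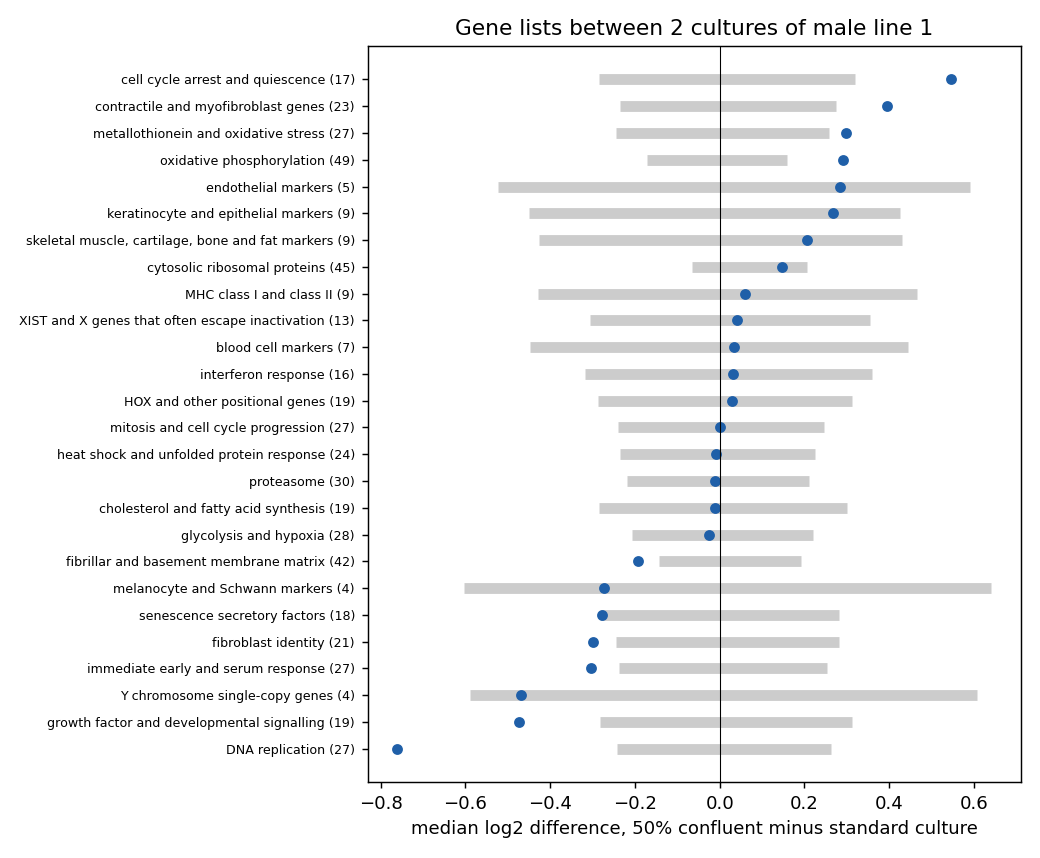
Median log2 difference of each gene list, 50% confluent minus standard culture of male line 1 (points), with the number of genes in parentheses and the central 95% of 10000 matched random lists (grey bars). DNA replication lies lowest at -0.76 and cell cycle arrest and quiescence highest at 0.55, which reversed to -0.035 with a floor at the 60th percentile.

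The distance between both cultures of male line 1 was set against distances between lines. It was 0.657 (root mean square log2), and 45 pairs of different lines spanned 0.576 to 0.856 with a median of 0.699. Of these pairs, 14 were closer than the cultures of the same line. Even so, the second culture of male line 1 was nearer to its own line than to any other standard line (0.687 to 0.837). The nearest of the others was male line 3, at 0.687. Without replicate cultures, this margin was not tested.

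Variation between the 10 standard lines was described last. The lipid carrier gene APOE had an SD of 2.12 log2 and ran from 100 in female line 3 and male line 3 to 8649 in female line 4. MYH11 (SD 1.96) was highest in female line 1 (6163), as were COL11A1 (4289), ACTC1 (3974) and DHRS3 (4674). Also of large SD were MMP1 (SD 1.91), COL11A1 (1.61), ELN (1.54), the gene of elastin, TNC (1.53), MMP3 (1.51), COL15A1 (1.45) and MXRA5 (1.41). EPB41L3, PSG9, NMB, TFAP2A, CCN5, MGLL and GABBR2 also stood among the 20 most variable genes, with RPS4Y1 (2.13) following sex. The patterning gene HOXC6 (SD 1.73) was at or near the floor in female lines 3 and 4 and male line 4 (100, 139 and 100) and read 829 to 1679 in the other 7 lines. These values come from 1 of its 3 tested probe sets. The other 2 had different log2 sex estimates (-0.08 and 0.39, against 0.98). Over 5370 genes the median SD was 0.43, and 121 genes had an SD over 1.

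Lists of mitosis (median SD 0.87), senescence-secreted factors (0.815), contractile genes (0.69), DNA replication (0.64), matrix (0.57) and fibroblast identity (0.57) were more variable than all 10000 matched random lists. UBE2C (SD 1.30), BIRC5 (1.25), CCL2 (1.30), IL6 (1.14), ACTA2 (1.25) and TYMS (0.92) were examples. Proteasome genes were the least variable list (median SD 0.27, percentile 0.01). HLA genes (median SD 0.46) and cytosolic ribosomal protein genes (0.31) lay inside the random range. Random lists of unrelated genes ignore correlation between members here too, so these ranks do not measure chance.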

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

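The tests of RNA degradation and of scaling in this part were chosen after the results they bear on had been seen.

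A line stood apart from the other 4 of its sex, or the other 9 lines, in 7 of 114 groups of values examined. That is close to the nominal chance rate of about 1 in 20. Many of the genes examined were named for low p or large SD in these same data, so this rate need not hold for them. Another 28 groups with more than 1 value at the floor were not examined. Male line 4 had low values for KDM5C (137, against 558 to 650 in the other males), UBA1 (2711, against 4897 to 6122) and HPGD (100, against 354 to 542). PUDP was at 100 in male line 3, against 253 to 280. In female line 1, LGR5 read 139, against 217 to 247. DDX3X read 1930 in female line 2, against 1090 to 1280. MXRA5 read 299 in female line 5, against 1334 to 7125 in the other 9 lines.

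MMP1 had opposite age slopes in females and males (limma, adjusted p of the difference 0.0458). Scaling between arrays is argued against for the size of the estimate, which was -4.61 ± 0.69 (SE) under quantile normalization and -4.53 ± 0.63 as deposited. Trimmed array means already lay within 3.57%, so this test had little room to move it. The call itself depended on scaling: the limma adjusted p rose to 0.124 under quantile normalization, and the call was also lost with median centring. Of 100 splits drawn from the 126 ways to part the 10 lines 5 and 5, 11 gave as many interaction calls, the real one included, the highest other being 42, so chance cannot be excluded. What set the split with 42 calls apart was not tested. Growth state may contribute, since MMP1 differed 18.6-fold with harvest state in male line 1. Over the 10 lines, MMP1 and the mean log2 of the mitosis list had r = -0.39 (permutation p = 0.264). Their rho was -0.58 (permutation p = 0.0872), and r was -0.50 without the 2 lines farthest from the median. That mean was 8.10 in the standard culture of male line 1 and 8.23 in its other culture, where MMP1 was lower. The mitosis mean thus barely followed harvest state, so this correlation cannot decide whether harvest state contributed. Growth state and a sex-dependent effect of age both stay open.

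Control probe sets for ribosomal RNA were bright in the 50% confluence culture: 2611, 2078 and 1508 for 18S (up to 300, 313 and 146 in the standard lines) and 2051 for the 5' 28S probe set (up to 959). Ribosomal RNA in the labelled sample may have shifted the harvest comparison. If so, male line 4, with 3945 on the middle 28S probe set against 4430 in the 50% confluence culture, would be expected to deviate alike, yet across 4497 genes the harvest difference correlated at r = 0.0748 with male line 4 minus the other lines (genes are not independent replicates). Its 18S signal was far weaker, so a bound of 0.1 set before the test was not a fair limit, and this explanation stays open. More degraded RNA in the 50% confluence culture is argued against by its ACTB 3' to 5' ratio of 0.669, below the 0.853 to 2.27 of all 10 standard lines. Its GAPDH 3' to 5' ratio of 0.815 lay inside their range, 0.691 to 1.67, and does not decide. The standard culture of male line 1 had 1.42 for ACTB and 1.17 for GAPDH. The 2 arrays compared thus also differed in these measures of RNA quality, and what that adds to the harvest differences stays open. Harvest density itself was not separable from that array.

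The male-higher mitosis list formed 1 correlated block. Its mean log2 was 8.78 ± 0.46 in males and 8.14 ± 0.82 in females (SD, n = 5 each), with an exact two-sided permutation p of 0.175, so allocation of lines with high and low mitotic expression to the sexes by chance could account for it. A poor array in the male group is argued against: the difference was 0.64 with male line 4 and 0.61 without it. Of the 100 splits, 85 gave at least the 3 lists called by sex, with up to 9, so chance cannot be excluded for that count, whereas 3 splits, the real one included, gave as many probe sets as the 2 called by sex (highest other 3). That share is under 0.05, the limit set before the test for excluding chance, though 1 of the 2, DDX3Y, did not pass in 9 of the 10 fits that left out 1 line. For the lists by age, 67 of 100 orders of the ages gave at least 4 lists, with up to 11. An effect of sex on mitotic genes remains untested beyond this.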

How the results depend on the processing

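The 96 single results had 1170 alternatives, of which 1115 counted as kept, 48 lost the call, 6 moved, 0 gained a call and 1 reversed. The reversed one was the median of the cell cycle arrest list by harvest state, at -0.035 with a floor at the 60th percentile. Most named genes by sex, age and interaction had not passed, so for them kept means the same direction and still not passing. Harvest differences and SDs have no such threshold and counted as kept near the main value. RPS4Y1 kept its call in all 10 fits that left out 1 line and in 9 of 9 others. DDX3Y kept it in 1 and 6 of these, and MMP1 by interaction in 1 and 4. The floor at the 20th percentile was also 100, so it repeated the main values and could only count as kept. Against 2 probe sets by sex, there was 1 with a floor at the 60th percentile, 1 with a pseudocount and 1 with all probe sets, and 0 with those above the floor in all 11 arrays, where RPS4Y1 and DDX3Y cannot be tested. Against 1 by interaction, there were 0 under quantile normalization, 0 with median centring, 0 with all probe sets, 0 without an intensity trend and 0 with array weights. Age gave 1 with all probe sets, against 0. Lists by sex numbered 1 with an estimated correlation and 1 with fry, against 3. Lists by age numbered 0 with an estimated correlation, 0 with fry and 8 with log2 of age, against 4. Harvest differences numbered 319 with a floor at the 60th percentile and 261 when also outside the range of the standard lines, against 592. The median SD was 0.367 with that floor and 0.366 as a median absolute deviation, against 0.425. The causes were not tested.

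Leaving out 1 line at a time gave 1 to 2 probe sets by sex, 0 to 0 by age, 0 to 1 by interaction, 2 to 5 lists by sex and 2 to 8 by age. Lists by age were 8 without female line 4, 7 without female line 1 and 2 without female line 2; lists by sex were 5 without male line 1 and 5 without female line 5. Chosen after seeing the data, leaving out pairs with male line 4 gave 14 of 36 line pairs closer than the cultures of the same line. The sex and age comparisons had no pairs, since each standard line came from a different animal and the line numbers pair nothing. Where a gene is at the floor, its fold is a bound.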

Other observations

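The tests in this part were written before their values were seen.

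Several HOX genes, which keep positional identity in fibroblasts, varied between the 10 lines. HOXB7 read 102 in female line 4 and 151 in female line 3 but 353 to 812 elsewhere. These were 2 of the 3 lines with little HOXC6 by the probe set used, 1 of 3 tested. In male line 4, the other line with little HOXC6, HOXB7 read 404. HOXC5 ran from 141 in male line 4 to 745 in male line 2, and TBX2 from 100 in female line 3 to 704 in female line 5. The homeobox gene MSX1 was highest in male line 4 (2173) and lowest in male line 5 (413). The biopsy site of each line is not given in the sources used here.

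Harvest state may move a culture along the main axis on which lines differ. The test for component 1 was negative: across 4497 genes the harvest difference had an absolute r of 0.0520 with component 1 of the 9 other lines, which held 22.3% of their variance. Male line 4 lay farthest out on this component (32.2) and female line 1 near the middle (-5.05), so the test does not bear on how far the 50% confluence culture resembled female line 1. Component 2 held 19.6% of the variance, nearly as much as component 1, and had an r of -0.27. This was the largest absolute r of the 8 components. The negative result therefore holds for component 1 alone, on which the array of male line 4 lay farthest out. Of the single lines, female line 1 minus the rest had the highest r, 0.255, and female line 2 the lowest, -0.209.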
